A study of Homo sapiens with 6 samples.

How the data were processed

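K562 cultures treated with FB23-2 or DMSO, 3 per group, were measured on 2-colour Agilent arrays with probes for mRNAs and long noncoding RNAs. Groups and replicate numbers were taken from the sample titles. Some source names and the series title spell the compound with another final digit; the titles and the design text give FB23-2. Per the labels the dose was 5 mM, which is high for such an inhibitor, and the unit could not be checked. Per the labels, total RNA was immunoprecipitated with an anti-m6A antibody, the IP fraction was amplified and coupled to Cy5 and the supernatant to Cy3. No dye swap was made, so a dye effect on single probes is part of every ratio. Whether that effect was equal on all arrays and in both groups was not tested.

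The scanner files hold linear intensity values from Agilent Feature Extraction 11.0.1.1, and per the file headers the processed signals were background-subtracted and dye-normalized by linear and lowess factors within each array. Each array held 62976 spots and 0 saturated spots. The authors also deposited a table with raw and normalized log2 IP signals for 38305 rows, with gene names. Each row matched 1 probe in the scanner files by its raw log2 values on all arrays (tolerance 1e-06, largest distance 5e-09, next nearest probe at 0.0201). Gene names were taken through this match. The names comprised 19161 genes, 32567 rows carried a symbol current in RefSeq GRCh38.p14, 1808 an older one, and 3930 matched neither. The files do not name the other probes. As a check, 43 probes that carry their own RefSeq accession were set against named probes of the same gene. The log ratios correlated at a Spearman rho of 0.694 across genes (highest of 1000 random namings 0.46), while IP levels did not (rho 0.031, highest random 0.371). Of 1897 pairs of probes with consecutive numbers, 1077 shared a gene name, against at most 1 after shuffling. The authors' normalized log2 values equal the raw ones minus 1 constant per array, between 9.09 and 10.2. The basis of that constant is not given in the sources used here. Medians of the authors' normalized columns were -2.07, -1.12 and -0.83 in DMSO and -0.87, -1.54 and -1.02 with FB23-2. The table holds IP signals alone and so gives neither measure used here. The number of per-sample columns left unused was 0.

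Control spots and spots marked as outliers were left out (192 to 538 outlier spots per array), and spots of 1 probe were averaged. The m6A ratio was log2 of processed Cy5 over Cy3, centred on each array's median. Probes well above background in both channels on at least 2 of 3 arrays of each group were tested. RNA abundance was log2 of the summed processed signals minus each array's 75th percentile. For it, probes well above background in either channel on at least 2 of 3 arrays of 1 group were tested. Probes whose difference could not be estimated after outlier removal were dropped. Requiring at least 2 unflagged values per group, a rule chosen after seeing the data, is given as an alternative. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, Benjamini-Hochberg at 0.05). The 33 gene lists, tests and most alternatives were fixed before the data were examined. Of the lists, 32 had at least 3 tested members; the list of erasers, with 2, was described by its genes. Lists were tested with camera (preset correlation 0.01, and estimated), and with fry beside it. Each gene entered by its brightest probe (highest mean log2 signal over both channels), and camera used members with values on all arrays, 27 of 28 in the integrated stress response and 43 of 53 ribosomal proteins in abundance. The overall ratio was compared by an exact permutation test.

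Named genes were chosen by a fixed rule applied to the brightest probe of each gene. In each measure these were up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold without overlap of groups. Where none passed, the 5 with the smallest p in each direction were named. Members of the m6A lists and up to 4 smallest-p members of each described list were added, as were up to 5 called long noncoding transcripts per direction. Genes are given under the array's names, some of them older ones, and without coordinates because the array design and the reference use different builds.

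The arrays were not duplicates: correlations between arrays ranged from 0.818 to 0.95 in the m6A ratio and 0.895 to 0.987 in abundance. Scan 1 held 5 arrays and scan 2 held DMSO replicate 3 alone, so values within scan 1 are those without that array, and a fit with scan as a term rests on the same arrays. The slide of each array is not given in the sources used here. The procedure was tested on simulated data with 200 changed probes. For abundance (38693 probes) limma recovered 6% of planted 2-fold, 90% of 4-fold and 100% of 8-fold changes, with 12 false calls. For the m6A ratio (29465 probes) it recovered 24%, 94% and 100%, with 14 false calls. Camera called the planted list and 0 of the others in each. The simulated probes varied independently, without correlation between genes or differences shared across an array. The simulation therefore does not show how often camera calls lists falsely on the real arrays. Alternatives covered background correction (normexp with an offset of 50, and background subtraction with a floor of 1, both on median spot signals because the files have no mean spot signal), dim-probe filters, normalization, single channels, replicate number, variance model and each array left out. Median background-subtracted signals per array were 10.0 to 24.0 in IP and 17.0 to 24.0 in supernatant, below the normexp offset of 50. An offset of that size makes log2 differences of dim probes smaller by construction.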

Results

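K562 is an established chronic myeloid leukaemia cell line. The cells were treated for 48 hours with FB23-2, an inhibitor of the m6A demethylase FTO, at a dose given as 5 mM, a unit in doubt, or with the solvent DMSO. Each group held 3 cultures, grown and harvested independently, and each culture was hybridised to 1 array. RNA bound by an antibody against N6-methyladenosine (m6A), here called the IP fraction, was coupled to the dye Cy5, and the unbound supernatant RNA of the same culture to Cy3. The ratio of the 2 signals was taken as the relative m6A level of a transcript, and their sum as a measure of its RNA abundance. The 2 fractions were labelled separately and scaled by dye normalization to similar medians. The sum therefore does not keep their true shares and stands for total RNA only approximately. Of 60541 probes on the array, between 29677 (DMSO replicate 1) and 37940 (DMSO replicate 3) were well above background in the IP channel. In the supernatant channel the range was 32786 to 39119. DMSO replicate 3 was scanned separately from the other 5 arrays and had the highest median processed IP signal, 210.9 against 86.7 to 136.9. Before dye normalization its median background-subtracted IP signal was not the highest. Its linear dye normalization factors were the largest in both channels, and its Cy5 detector voltage was lower than on the other arrays. The number of arrays, 3 per group, limits the precision of every comparison.

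The first comparison asked whether the overall m6A level differed between inhibitor and solvent. The median log2 ratio of IP to supernatant over tested probes was -0.08 ± 0.03 (SD, n = 3) in DMSO and -0.11 ± 0.08 (SD, n = 3) with FB23-2, a difference of -0.03 (exact two-sided permutation test, p = 0.7). The smallest p that 3 against 3 arrays allow is 0.1. The dye normalization in the scanner software brings each array's median ratio close to 0, so these signals could not show a shift shared by most transcripts. Without that normalization the medians spread widely within each group, at -0.12 ± 0.45 in DMSO and 0.01 ± 0.45 with FB23-2 (SD, n = 3 each; exact permutation p = 0.8). Relative to the 2 ERCC control probes above background on all arrays, the medians were 1.25 ± 0.12 in DMSO and 1.05 ± 0.42 with FB23-2 (SD, n = 3 each; exact permutation p = 0.6). The difference pointed down in the normalized signals and up without dye normalization (0.13). Relative to the control probes it pointed down both with dye normalization (-0.20) and without (-0.19; exact permutation p = 0.6), but the 2 control probes disagreed: relative to each alone the difference was 0.15 and -0.56.

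The second comparison asked which transcripts changed their m6A ratio relative to the rest of the array. No single transcript passed the threshold. Of 29465 tested probes, limma called 0 at a Benjamini-Hochberg adjusted p of 0.05, and 465 had an unadjusted p under 0.05, against 1473 expected by chance. The transcripts with the smallest p among higher ratios were RWDD3, HIST1H2AI, RP11-446H18.3, AC007773.2 and CHRNA5. RWDD3, a regulator of protein SUMOylation, had a log2 ratio of 1.56 ± 0.28 in DMSO and 2.72 ± 0.21 with FB23-2 (SD, n = 3 each; limma adjusted p = 1). The differences were 1.46 for the histone gene HIST1H2AI, 1.26 for RP11-446H18.3, 1.14 for AC007773.2 and 0.99 for the nicotinic receptor subunit gene CHRNA5. Among lower ratios the smallest p belonged to RP11-103J17.1, RP4-756G23.5, TREML2, CRYBG2 and RP11-501C14.5, with differences of -1.01, -1.20, -1.17, -0.99 and -0.91. None of these 10 passed, each with a limma adjusted p of 1.

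The genes of the m6A machinery and reported FTO targets had no member past the threshold in either measure. For FTO itself the m6A ratio differed by -0.14 (SE 0.31) and its RNA abundance by 0.17 (SE 0.39). The other demethylase gene, ALKBH5, differed by 0.21 (SE 0.37) in m6A ratio and 0.08 (SE 0.38) in abundance. For the writer genes METTL3, METTL14 and WTAP, the m6A ratio differed by 0.52, 0.47 and 0.23, and abundance by 0.44, -0.06 and 0.10. The reported FTO targets MYC, ASB2 and RARA differed by 0.06, 0.04 and -0.23 in m6A ratio and by -0.00, 0.31 and -0.07 in abundance. Directions for FTO, ALKBH5, MYC and ASB2 in the ratio, and for these and METTL14, WTAP and RARA in abundance, flipped under other settings. Over all 36 tested writers, erasers, readers and reported targets, 0 had an unadjusted p under 0.05 by limma in either measure. The smallest p was 0.0871 in the ratio and 0.189 in abundance.

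Taken as groups, 4 of the 32 tested gene lists had a higher m6A ratio with FB23-2 than other genes by camera, and 0 had a lower one. With an estimated correlation all 4 calls were lost, with an adjusted p of 0.793 for each list. Replication histone transcripts had a median log2 difference of 0.34, and 16 of 21 were higher (camera adjusted p = 0.00132; adjusted p = 0.793 with an estimated correlation). Examples were HIST1H2AC and HIST1H2AB, with differences of 0.68 (SE 0.28) and 0.69 (SE 0.30). Transcripts of m6A readers, proteins that bind the mark, had a median difference of 0.28, and 14 of 15 were higher (camera adjusted p = 0.00418). Among them YTHDC2 differed by 0.55 (SE 0.29) and YTHDF3 by 0.40 (SE 0.36). Known long noncoding RNAs had a median difference of 0.16, with 20 of 26 higher (camera adjusted p = 0.0197). MIR17HG differed by 0.74 (SE 0.29) and MALAT1 by 0.93 (SE 0.40), while LINC-PINT and NEAT1 differed by -0.60 and -0.46. The 2 tested NEAT1 probes disagreed in direction. Genes of G2 and mitosis had a median difference of 0.19, with 20 of 27 higher (camera adjusted p = 0.0275), among them BUB1B at 0.52 and MKI67 at 0.46 (0.10 to 0.78 with single arrays left out). No member of these 4 lists was called over all genes, and the count adjusted over the list alone was 0 in each. Fry gave an adjusted p of 0.988 for each of them. Within the 5 arrays of the first scan 0 of the 32 lists passed.

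RNA abundance differed for a small set of transcripts, and most of these fell with FB23-2. Limma called 47 of 38693 tested probes at an adjusted p of 0.05, of which 41 fell and 6 rose. They carried 39 gene names, and 26 genes were called by their brightest probe. Of the 47 probes, 16 were not well above background on any FB23-2 array, and 1 was not on any DMSO array. The differences of those probes rest in part on signals near background. Without DMSO replicate 3, which leaves the 5 arrays of the first scan, 148 probes were called, 83 higher and 65 lower, and 44 of the 47 remained. With quantile normalization 13 were called, 0 higher and 13 lower, with normexp background correction 2, and with scaling to the control probes 0 (104 at an unadjusted p under 0.05). Abundance is given below as log2 of the summed signals relative to each array's 75th percentile. The median difference over all tested probes was 0.08.

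**Figure D1:**
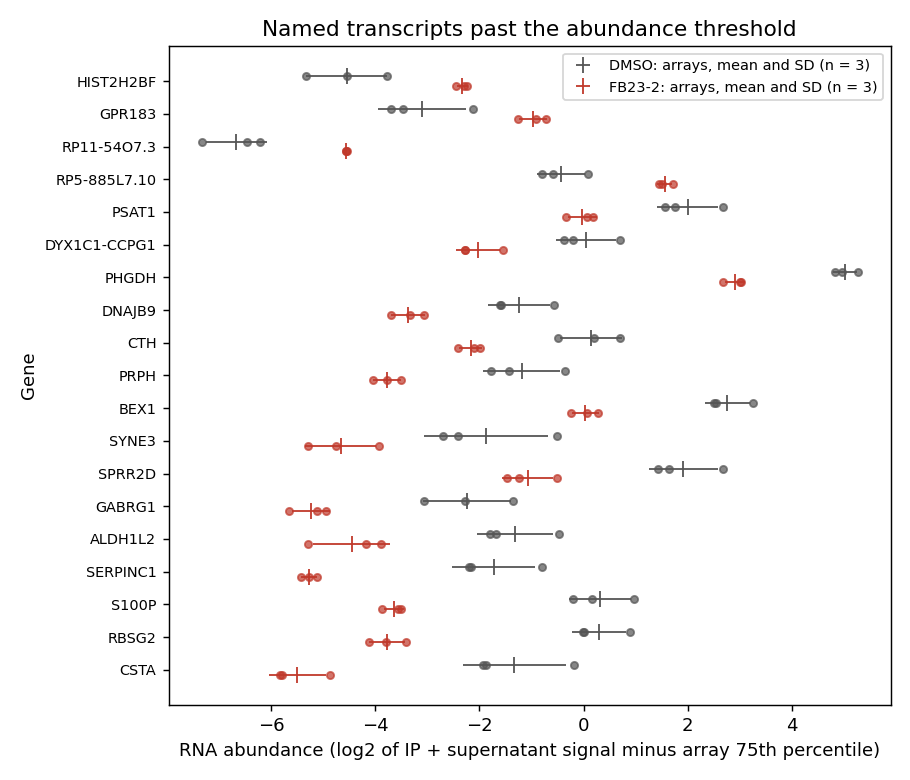
RNA abundance (log2 of IP plus supernatant signal minus the array's 75th percentile) of the 19 named genes past the threshold; points are arrays, bars the mean and SD of 3 DMSO (grey) and 3 FB23-2 (red) arrays. The 4 genes at the top are higher with FB23-2, the others lower.

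CSTA, which encodes the protease inhibitor cystatin A, fell from -1.33 ± 1.00 in DMSO to a level not well above background on any FB23-2 array, at least 12.1-fold lower (n = 3 each; limma adjusted p = 5.21e-05). Both tested CSTA probes were called. S100P, a calcium-binding protein gene, fell from 0.31 ± 0.60 to -3.64 ± 0.19, 15.5-fold (SD, n = 3 each; limma adjusted p = 1.84e-05). RBSG2, a name not matched to a current gene symbol, fell by 4.07 on the log2 scale (SE 0.39; adjusted p = 1.84e-05). SERPINC1, the gene of antithrombin, was not well above background on any FB23-2 array and was at least 9.74-fold lower (adjusted p = 0.000121). SPRR2D, a gene of the cornified envelope of skin cells, fell from 1.92 ± 0.67 to -1.08 ± 0.50, 7.95-fold (SD, n = 3 each; limma adjusted p = 0.00165). BEX1 fell 6.62-fold, from 2.76 ± 0.43 to 0.04 ± 0.27 (SD, n = 3 each; limma adjusted p = 0.00165). PRPH, which encodes the neuronal filament protein peripherin, fell 5.99-fold. GABRG1, a GABA receptor subunit gene, and SYNE3 were well above background on 1 of 3 FB23-2 arrays only, so their fitted log2 differences of -3.00 and -2.79 rest in part on signals near background. Among called genes matched to RefSeq, only the readthrough DYX1C1-CCPG1 was typed as long noncoding. It fell 4.23-fold (limma adjusted p = 0.0349) and did not pass without any 1 of the 3 FB23-2 arrays. RBSG2, and RP11-54O7.3 and RP5-885L7.10, which rose, matched no current symbol, so whether they are noncoding is not given here. SYNE3 did not pass without DMSO replicate 3, and neither SYNE3 nor PRPH without FB23-2 replicate 1. The other tested SYNE3 probe differed by -0.70 and was not called. With normexp BEX1 and PHGDH alone passed among the 19 named genes, and the log2 differences of dimmer genes were much smaller: -1.86 for S100P, -1.87 for RBSG2, -1.09 for CSTA, -0.90 for SERPINC1, -0.999 for PRPH, -0.71 for GABRG1, -0.81 for SYNE3 and -1.21 for DYX1C1-CCPG1. The bounds given as at least a fold hold for the processed signals only.

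The genes that rose were HIST2H2BF, GPR183, RP11-54O7.3 and RP5-885L7.10. HIST2H2BF, a histone H2B gene, rose 4.67-fold, from -4.55 ± 0.78 to -2.33 ± 0.11 (SD, n = 3 each; limma adjusted p = 0.0252), and was above background on 2 of 3 DMSO arrays. GPR183, an oxysterol receptor gene, rose 4.38-fold, from -3.10 ± 0.85 to -0.97 ± 0.27 (SD, n = 3 each; limma adjusted p = 0.0418). RP5-885L7.10 rose 3.95-fold by its brightest probe (limma adjusted p = 0.0341). Its 3 tested probes differed by 0.52 to 1.98, and 1 of them passed. RP11-54O7.3 was well above background on 2 of 3 FB23-2 arrays and not well above background on any DMSO array, and was at least 1.55-fold higher in the processed signals (adjusted p = 0.0252). Without FB23-2 replicate 1, none of these 4 genes passed, and in all 14 probes were called. GPR183 and RP5-885L7.10 did not pass without DMSO replicate 2 either, nor RP5-885L7.10 without FB23-2 replicate 3. With normexp the differences of HIST2H2BF, GPR183, RP11-54O7.3 and RP5-885L7.10 were 0.43, 0.90, 0.16 and 1.52, and none passed.

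Transcripts of the integrated stress response, the programme driven by the transcription factor ATF4, fell as a group. Of 28 tested members 18 were lower, with a median difference of -0.38 (camera adjusted p = 2.88e-18). This was the only list still called with an estimated correlation, with an adjusted p of 0.0208, and fry gave an adjusted p of 0.0166. Over all genes 4 members were called lower, and 9 when adjusted over the list alone. The 4 encode enzymes of serine, cysteine and mitochondrial folate metabolism. PHGDH, the first enzyme of serine synthesis, fell from 5.02 ± 0.23 to 2.90 ± 0.19, 4.33-fold (SD, n = 3 each; limma adjusted p = 0.015). PSAT1, the next enzyme of that pathway, fell 4.05-fold by its brightest probe, and both of its tested probes were called. CTH, which makes cysteine from cystathionine, fell 4.95-fold (adjusted p = 0.0125). ALDH1L2, a mitochondrial folate enzyme, fell 8.76-fold (adjusted p = 0.00165) and was above background on 2 of 3 FB23-2 arrays. The second PHGDH probe differed by 0.18 and the third CTH probe by 0.61, so probes of these 2 genes disagreed. Without FB23-2 replicate 1, CTH, PHGDH and PSAT1 did not pass, nor did PSAT1 without FB23-2 replicate 2. With normexp ALDH1L2 and CTH differed by -0.98 and -1.36 and did not pass. Within the first scan the list was again lower (camera adjusted p = 1.9e-08; adjusted p = 0.253 with an estimated correlation).

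The unfolded protein response, the response to misfolded protein in the endoplasmic reticulum, had the lowest median of the 32 lists. Of 17 tested members 15 were lower, with a median difference of -0.70 (camera adjusted p = 4e-19). This call was lost with an estimated correlation (adjusted p = 0.126), and the list did not pass with fry (adjusted p = 0.166). The co-chaperone gene DNAJB9 was the 1 member called over all genes and fell 4.33-fold (adjusted p = 0.0282), while 5 were lower when adjusted over the list alone. DNAJB9 did not pass without FB23-2 replicate 1 or 2, nor with normexp, where it differed by -0.85. XBP1, the transcription factor of this response, was 4.45 ± 0.28 in DMSO and 3.05 ± 0.21 with FB23-2 (SD, n = 3 each; limma adjusted p = 0.291). Its other tested probe differed by -0.40. HSPA5, the chief chaperone of the endoplasmic reticulum, differed by -1.42 (SE 0.41) and SEL1L by -1.85 (SE 0.42). Within the first scan it was lower (camera adjusted p = 1.58e-05; adjusted p = 0.335 with an estimated correlation). The list shared 0 tested members with the integrated stress response list.

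Cytosolic heat shock genes were higher as a group, with a median difference of 0.39 and 13 of 15 members higher (camera adjusted p = 4.07e-05; adjusted p = 0.126 with an estimated correlation). HSPA8 was 2.24 ± 0.57 in DMSO and 3.50 ± 0.43 with FB23-2 (SD, n = 3 each; limma adjusted p = 0.66), and DNAJA1 differed by 0.82 (SE 0.41). The 3 tested HSPA8 probes differed by 0.03 to 1.26. Over all genes 0 members were called by limma, and 3 were higher when adjusted over the list alone. The list of genes of cholesterol metabolism and its SREBP regulators had a median difference of 0.24, and 21 of 24 were higher (camera adjusted p = 0.000507; adjusted p = 0.126 with an estimated correlation). MSMO1 and INSIG1 differed by 1.11 (SE 0.41) and 1.06 (SE 0.41). Both calls were thus lost with an estimated correlation. Neither list passed with fry (adjusted p = 0.166 for heat shock and 0.0907 for cholesterol). Within the first scan both lists passed by camera, with adjusted p of 3.13e-07 and 0.00308 (0.253 for each with an estimated correlation), while without DMSO replicate 2 the heat shock call was lost (0.053).

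Replication histone transcripts were higher in abundance too, 17 of 21, with a median difference of 0.12 and a mean of 0.37 (camera adjusted p = 0.000507; adjusted p = 0.576 with an estimated correlation). The median over all genes was 0.095, so the middle of the list lay close to other genes and the higher mean rests on part of it. HIST1H2AG, HIST1H3H and HIST2H2BE differed by 1.62, 1.49 and 1.45, with 3 members higher when adjusted over the list alone and 0 over all genes. Ribosomal protein transcripts were lower, 36 of 53, with a median difference of -0.15 (camera adjusted p = 5.39e-05; adjusted p = 0.0982 with an estimated correlation). RPL3 differed by -0.67 (SE 0.37). Targets of E2F at the G1 to S transition were lower, 23 of 29, with a median difference of -0.18 (camera adjusted p = 0.000507; adjusted p = 0.576 with an estimated correlation). E2F2 and CDT1 differed by -1.07 (SE 0.41) and -0.70 (SE 0.39). In these last 2 lists 0 members were called by either adjustment. With fry none of the histone, ribosomal and E2F lists passed (adjusted p = 0.166, 0.0907 and 0.757). Within the first scan the E2F call was lost (camera adjusted p = 0.948), while the histone and ribosomal lists passed (7.66e-07 and 0.00551; 0.253 and 0.468 with an estimated correlation). The histone call was lost without DMSO replicate 1 or 2 (camera adjusted p = 0.112 and 0.137).

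**Figure D2:**
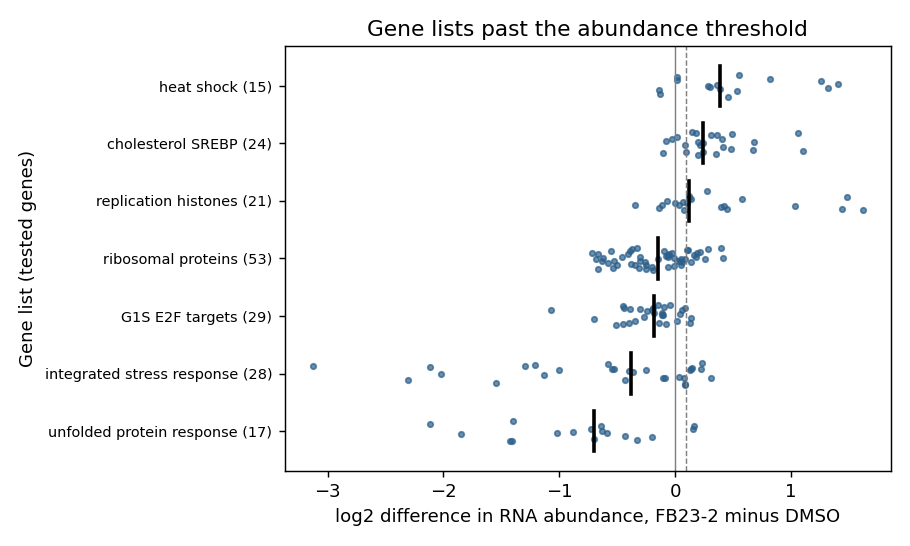
Log2 difference in RNA abundance (FB23-2 minus DMSO) of each tested gene in the 7 lists past the threshold; points are genes, black bars list medians, the solid line 0 and the dashed line the median of all genes. The integrated stress response and unfolded protein response lists have medians of -0.38 and -0.70, the heat shock list 0.39.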

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

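The array weights, the covariate, the rule on flagged spots, the authors' IP signal for abundance the control spots without dye normalization and the estimated correlation within the first scan were chosen after the results were seen. The cause of the differences below was not tested. The authors' table could not be run for m6A ratio calls or lists because it holds IP signals only, nor was a slide block, as the slides are not known.

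For the m6A ratio limma called 0 probes in every setting, with 166 (normexp) to 3179 (array weights) at an unadjusted p under 0.05. For RNA abundance, called in 47 probes, the counts were 2 with normexp, 14 with background subtraction, 14 with both channels above background on all arrays, 89 without a filter, 13 with quantile normalization, 0 scaled to ERCC spots (104 at unadjusted p under 0.05), 20 in the supernatant alone, 18 in IP alone, 0 in the authors' IP signal (276 at unadjusted p under 0.05) and 26 by gene. With array weights it was 3942, 2551 higher and 1391 lower; that fit did not converge, with weights from 0.02 to 51.4. With at least 2 unflagged values per group it was 45. Leaving out single arrays gave 14 (FB23-2 replicate 1) to 148 (DMSO replicate 3), and 137 without DMSO replicate 1. The 19 named genes past the threshold kept their direction in 367 of 367 alternative values and passed in 255. Their groups did not overlap, so leaving out an array could not turn their direction, and the other settings reused the same arrays. The kept direction is thus little evidence beyond the call itself.

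With the replicate number as a block, 173 probes were called in abundance, 0 in the m6A ratio, and 7 and 4 lists. In the pairing check arrays of the same number correlated at -0.306, -0.461 and 0.139 in the ratio and -0.383, 0.497 and 0.33 in abundance. Arrays of unlike number correlated at -0.283 to 0.501 in the ratio and -0.607 to 0.559 in abundance. The check thus gave no clear sign of pairing, but so few pairs cannot exclude it.

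The overall m6A difference of -0.03 was 0.067 with normexp, 0.134 with background subtraction, and -0.07 to 0.014 with arrays left out, highest without FB23-2 replicate 1. The authors' IP signal, which has no supernatant part and does not measure the ratio, differed by 0.195. The 4 lists of the m6A ratio became 0 with an estimated correlation and 7 with the mean of a gene's probes. With normexp they became 7, of which 6 were higher and 1 lower. The lower list was the unfolded protein response (camera adjusted p = 0.044). With arrays left out the count was 0 (without DMSO replicate 3) to 5 (without DMSO replicate 2). Without DMSO replicate 1, FB23-2 replicate 1 and FB23-2 replicate 3 it was 1, 1 and 2. The 7 abundance lists became 1 with an estimated correlation, 0 when this was combined with leaving out DMSO replicate 3 (also 0 in the ratio), and 6 to 11 with arrays left out, 11 without DMSO replicate 3.

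Of 641 gene values in the ratio 624 kept their label and 17 turned. No ratio probe passed in any setting, so there a kept label means only that the sign held. Some of these genes had been chosen for their smallest p. Of 1175 values in abundance 955 kept their label, 164 were weaker, 26 stronger and 30 turned. Of 48 list values in the ratio 27 held and 21 were weaker, and of 84 in abundance 67 held and 17 were weaker.

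The values that turned in the m6A ratio were FTO 0.011 (array weights); MYC -0.021 (normexp), -0.118 (background subtraction), -0.145 (centred on ERCC spots) and -0.224 (percent modified); ASB2 -0.029 (loess) and -0.164 (ERCC spots); and MKI67 -0.045 (array weights). With arrays left out FTO ranged from -0.309 to 0.098, ALKBH5 from -0.2 to 0.553, MYC from -0.201 to 0.42, ASB2 from -0.118 to 0.192 and MKI67 from 0.104 to 0.783.

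In RNA abundance they were FTO -0.435 (array weights), ALKBH5 -0.002 (normexp) and -0.031 (supernatant), WTAP -0.05 (supernatant) and ASB2 -0.259 (array weights). METTL14 was 0.047 (IP alone), 0.218 (authors' IP) and 0.436 (array weights). MYC was 0.057 (normexp), 0.044 (background subtraction), 0.014 (IP alone), 0.186 (authors' IP) and 0.119 (array weights). With arrays left out FTO ranged from -0.078 to 0.369, ALKBH5 from -0.086 to 0.334, METTL14 from -0.309 to 0.442, WTAP from -0.101 to 0.43, MYC from -0.218 to 0.215, ASB2 from -0.278 to 0.657 and RARA from -0.278 to 0.054.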

Other observations

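The use of the scan, of loess and of a shared m6A shift as tests, the p with an estimated correlation in the 3 tests of the integrated stress response, and the counts over other splits of the arrays were chosen after the results were seen. The medians of the supernatant channel and of bright probes as tests, and the estimated correlation for the lists as a whole, were set out before.

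Globin and haem genes, which mark the erythroid side of K562 cells, were measured at 37 genes, of which 25 were higher with FB23-2. Their median log2 difference was 0.16, against 0.095 over all genes. HBB was -0.43 ± 0.37 in DMSO and 0.86 ± 0.12 with FB23-2 (SD, n = 3 each; limma adjusted p = 0.454). The embryonic globins HBE1 and HBZ differed by 0.78 (SE 0.37) and 0.65 (SE 0.36), and ALAS2, the first enzyme of haem synthesis in red cells, by 0.88 (SE 0.39). The list did not pass with camera (adjusted p = 0.177) or fry (adjusted p = 0.0907). It passed by camera within the first scan (adjusted p = 0.00626) and with normexp (adjusted p = 0.0196), both at the preset correlation. With an estimated correlation the adjusted p was 0.395 with all arrays and 0.253 within the first scan. Other marker lists, none of which passed with all arrays, were mostly higher too. These were myeloid differentiation, 14 of 18 (median 0.21), megakaryocytic genes, 11 of 13 (0.09), and markers of other cell types, 13 of 14 (0.19). The direction was thus not particular to erythroid genes.

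Probes of 1 gene often disagreed. Of the genes with a called abundance probe, 13 were called by a dimmer probe and not by the brightest. The following 3 were chosen after their values were seen. All 3 called probes of TM6SF1 were lower, by -2.44 to -2.35, while its brightest probe, 1 of 6 tested, differed by 0.14 (SE 0.38). For PCK2, a mitochondrial enzyme gene of the integrated stress response, the called probe differed by -2.01 and the brightest by 0.12 (SE 0.37). For ADARB1, an RNA-editing enzyme gene, 2 of 7 tested probes were called higher, by 2.03 and 2.27, while the brightest differed by 0.30 (SE 0.37).

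The lower abundance of integrated stress response transcripts was weighed against 3 technical explanations. If the separately scanned DMSO array had produced it, the list would return to the level of other genes without that array. Its median difference there was -0.34, with 26 of 28 members lower, but the median of all genes moved as well, to -0.10. Relative to all genes the shift was -0.47 with all arrays and -0.23 without that one (camera p = 0.0165 with an estimated correlation, 0.253 when adjusted over the lists). This argues against that array as the whole cause, and a part of the shift may depend on it. If it came from the IP fraction only, the supernatant channel would not show it; the median there was -0.28, with 18 of 28 lower (camera p = 0.00249 with an estimated correlation). Among the 25 members above background in both channels on all arrays the median was -0.26, with 15 of 25 lower (camera p = 0.00102 with an estimated correlation), which argues against dim probes as the whole cause. Members went both ways in the last 2 tests, so the lower level belongs to part of the list. A response of the cells to FB23-2 stays open as a hypothesis, as does any difference between the cultures that followed the treatment, since the list was found and tested on the same 6 arrays. Without the 4 called members, a subset chosen after seeing the data, the list was still lower (median -0.18, camera p = 1.64e-07, p = 0.00619 with an estimated correlation).

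The higher m6A ratio of 4 gene lists was weighed against 2 technical explanations. With loess within arrays 4 of the 4 lists still passed by the preset camera test. The signals had already been smoothed by lowess, and loess changed the log2 differences by an SD of 0.046 only, so that step decides nothing about a dye bias that depends on brightness. All 4 calls were lost with an estimated correlation (adjusted p = 0.793). Without the separately scanned DMSO array 0 of the 4 passed. Leaving out DMSO replicate 1 or FB23-2 replicate 1 left 1, so a part played by that scan cannot be told apart from the loss of an array. The main axis of the m6A ratio, 47% of the variance, did not follow treatment: DMSO replicate 1 and FB23-2 replicate 2 scored -57.8 and -52.5, and the other arrays between -2 and 67.8. Those 2 arrays also had the fewest IP probes above background, 29677 and 29989. In abundance the first axis held 68% of the variance and set DMSO replicate 3 (150.2) apart from the other arrays (-60.6 to 13.8). Scores on this axis ranked all arrays in the order of their median processed IP signals, from 86.7 (DMSO replicate 1) to 210.9 (DMSO replicate 3). The axis thus followed processed signal level over all arrays, not that array alone. Median background-subtracted IP signals before dye normalization did not follow the same order.

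A hypothesis that transcripts fell in abundance through a change of their m6A level was tested on the 17 lower probes that could be tested in both measures. Their median m6A ratio difference was 0.005, with 7 lower (camera p = 0.127, and p = 0.502 with an estimated correlation). Members went both ways, so the test decides nothing about single transcripts. CRYBG2, named above among the lower ratios, was also called lower in abundance, by -2.05 on the log2 scale (limma adjusted p = 0.0291). Its ratio difference of -0.99 did not pass.

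The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. For abundance the real split called 47 probes and the highest of the others 0, so 1 of 10 splits reached the real count. Another split, DMSO replicates 1 and 2 with FB23-2 replicate 2 against the rest, had 11100 probes at an unadjusted limma p under 0.05. The real split had 1019. Those 3 arrays had the lowest median processed IP signals, 86.7 to 88.2 against 108.9 to 210.9. That split thus followed signal level, which points to a structure of the arrays that centring on the 75th percentile did not remove. For the m6A ratio limma called 0 probes in the real split and in the others, so all 10 reached it; unadjusted p under 0.05 came to 465 and at most 6313. Of the gene lists, 4 passed in the m6A ratio and at most 10 in another split (3 of 10 splits had as many). In abundance 7 passed and at most 10 in another split (5 of 10 had as many).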
